A study of Drosophila melanogaster with 51 samples.

How the data were processed

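Chromatin was profiled by CUT&RUN, in which an antibody directs a nuclease to its target and the released DNA fragments are sequenced, in wing imaginal discs of female third-instar larvae of Drosophila melanogaster. Per the labels, each of the 51 libraries came from at least 20 discs of larvae kept at 25 °C, and the libraries fall into 18 groups by genotype, antibody and, where given, fraction. No values of single libraries were analysed here, so depth per library is unknown, no spread between replicates could be measured, and genotypes were not compared.

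What was analysed are 3 peak lists of the whole series, of H3K9me3, of HP1 and of background regions from an anti-GFP profile named yw. The titles of the yw anti-GFP libraries give yw, while their genotype label gives GFP-HP1a/+. If the latter holds, the background regions may include tagged HP1a. Per the submitters' processing notes, the tools include Bowtie2 2.3.4.1, SAMtools 1.10, bedtools 2.26 and MACS2 2.1.2, and the build is dm6. The deposited score of each peak equals 10 times its −log10 q-value, rounded down. The fold enrichment, a ratio of signal to the caller's expectation, and the −log10 p-value and −log10 q-value are the authors' values for each called peak. They were used only within a list, to describe, rank or filter peaks and, for the fold enrichment, to compare shared with unshared peaks. In the H3K9me3 list 54.0% of the intervals do not contain the summit recorded for them, against 73.5% in the HP1 list and 10.0% in the background list, and several intervals can carry the name of 1 call. Many intervals are therefore parts of a called peak, and their fold and q-value describe the whole call. Peak names in the H3K9me3 list point to an HWT library for 2047 intervals and to another source, named ywdf, for 198. All names in the HP1 list carry ywdf and the word merge. What ywdf stands for and how the calls were combined are not given in the sources used here. Each listed interval is called a peak in what follows.

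Chromosome positions were sorted into compartments. These, the gene lists, the tests and the rule for named genes were fixed before the data were examined. Pericentric parts were the centromere-proximal 1.5 Mb of 2L, 5.4 Mb of 2R, 5.1 Mb of 3L, 4.6 Mb of 3R and 0.9 Mb of X. Chromosome 4 and Y were kept apart, and the rest of 2L, 2R, 3L, 3R and X is called the arms. Chromosome ends were taken as the largest coordinate in the lists or the gene table. Genes came from a RefSeq table of Release 6 plus ISO1 MT, the assembly also called dm6, with 17807 genes on these chromosomes, 13946 of them protein-coding. The table gives gene starts and ends, and strand, exons, introns and transposable elements were not used here. The planned classes of transcription start site, exon, intron and transposon were therefore replaced by 2 classes, within 200 bp of either annotated gene end and within a gene body.

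A peak was shared if at least 1 bp lay in a peak of the other list. Overlap was compared with 1000 circular shifts of the peaks within each chromosome and compartment, and p is the doubled smaller tail, at smallest 0.002. Shares carry exact binomial (Clopper-Pearson) 95% intervals. The fold of covered bases over the arms has a 95% interval from 1000 bootstrap draws of 0.5 Mb blocks. Classes of peaks and gene lists were compared with Fisher's exact test, two-sided, and medians of width and fold enrichment with a permutation test of 100000 resamples, at smallest p = 1e-05. Adjusted p-values follow Benjamini-Hochberg, with a threshold of 0.05. Neighbouring peaks and genes are not independent replicates, so intervals and p-values describe these lists and not the variation between animals. Comparisons of overlap shares between compartments, and of positions by the middle base of a peak, were added after the lists had been seen.

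The 177 names in the 8 gene lists gave 172 genes of the gene table. SNAP25, dADD1 and Hsrω were further names of genes already listed, and Dl and nos were left out because the name fitted more than 1 gene. The rule for named genes let any list member be named, and took 2 to 4 of each list by the share of the gene body covered in either peak list. It also took the 8 protein-coding arm genes with the most covered bases in each class of peak, and the 5 widest arm peaks of each list. Beyond that ranking, all wing disc genes under HP1 and the chromosome 4 list genes under neither mark were named, chosen by their values.

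The tests were first tested on simulated data. Of 100 sets of 1432 HP1 peaks scattered at random, 2 passed the shift test. With 5% of the HP1 peaks moved onto H3K9me3 peaks, 100 of 100 sets passed. The scattered peaks were placed singly and evenly within each compartment, and with fewer shifts. The real peaks are clustered, so these rates need not hold for the lists. Of 100 random gene lists 5 passed Fisher's test over 13946 genes. Alternatives covered the overlap that counts as shared, a stricter q-value, background regions, merged peaks, the pericentric ends, the reach of a gene end, the rule for a gene under a peak and lists matched on gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.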

Results

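The series profiled heterochromatin in wing imaginal discs, the larval tissue that forms the adult wing and notum, with 15 libraries for H3K9me3, 16 for HP1a, 14 for GFP and 6 for H3K27me3. H3K9me3 is the histone mark bound by the chromodomain of HP1a. The genotypes include discs with wild-type (HWT) or lysine-to-arginine (K9R) replacement histone H3, an HP1a chromodomain mutant with its control, GFP-tagged HP1a and yw. The values below come from peak lists of the whole series and describe where H3K9me3 and HP1 were called, not how genotypes differed. The H3K9me3 list holds 2245 peaks over 1377 kb, with a median width of 372 bp and a median fold enrichment of 5.70 as the authors' caller gave it. The HP1 list holds 1435 peaks over 1110 kb, with a median width of 438 bp and a median fold enrichment of 6.03. The background list, from an anti-GFP profile titled yw whose genotype label reads GFP-HP1a/+, holds 500 regions over 451 kb.

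The first comparison asked where along the chromosomes the mark and its reader were found. H3K9me3 peaks lay in the pericentric parts in 83.3% of cases, and covered 6.11% of the pericentric bases (95% interval 4.43 to 7.97) and 0.0531% of the arms, a fold of 115 (48.5 to 362). Chromosome 4, a small and largely heterochromatic chromosome, was covered over 18.0% of its length by H3K9me3 and 18.8% by HP1. HP1 covered 3.17% of the pericentric bases and 0.265% of the arms, a fold of 12 (7.02 to 18.8). The arms held 612 HP1 peaks, 42.6% of that list, against 137 H3K9me3 peaks, 6.10% of that list. By the call numbers in the peak names, 8.60% of the HWT H3K9me3 calls spanned in the arms and 65.7% of those in the pericentric parts were listed. For HP1 the shares were 8.25% and 21.7%. For the ywdf H3K9me3 calls they were 9.21% and 5.95%. Numbers were counted only from the first to the last listed call of each chromosome part, so each share is an upper limit. The ywdf arm share rests on 76 numbers and cannot be set against the pericentric one. Chromosome 4 stood above the arms by a fold of 339 for H3K9me3 (151 to 984) and 70.9 for HP1 (52.6 to 96.1), with only 3 blocks behind these intervals. With pericentric parts 0.5 Mb smaller, the pericentric fold for H3K9me3 was 27 and that for HP1 6.71, and the chromosome 4 fold for H3K9me3 was 83.1. With these parts 0.5 Mb larger, the H3K9me3 folds were 217 and 708, and with the stricter q-value that of chromosome 4 was 552.

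The pericentric part of 2R held 762 H3K9me3 and 235 HP1 peaks, and that of 3L held 714 and 173. In the pericentric part of X there were 45 H3K9me3 peaks and 2 HP1 peaks, in a part that also held 100 background regions. The arm of 2R held 84 of the 137 arm H3K9me3 peaks. A run of 58 H3K9me3 peaks and 45 HP1 peaks at 2R 5400470 to 5701938 adjoined the pericentric end and spanned stw, Ugt50B3, Not3 and CG8245. The Y chromosome sequence held 22 H3K9me3 peaks, 3 HP1 peaks and 17 background regions. The discs are described as female, so these peaks need not come from a Y chromosome, and their source was not tested.

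**Figure D1:**
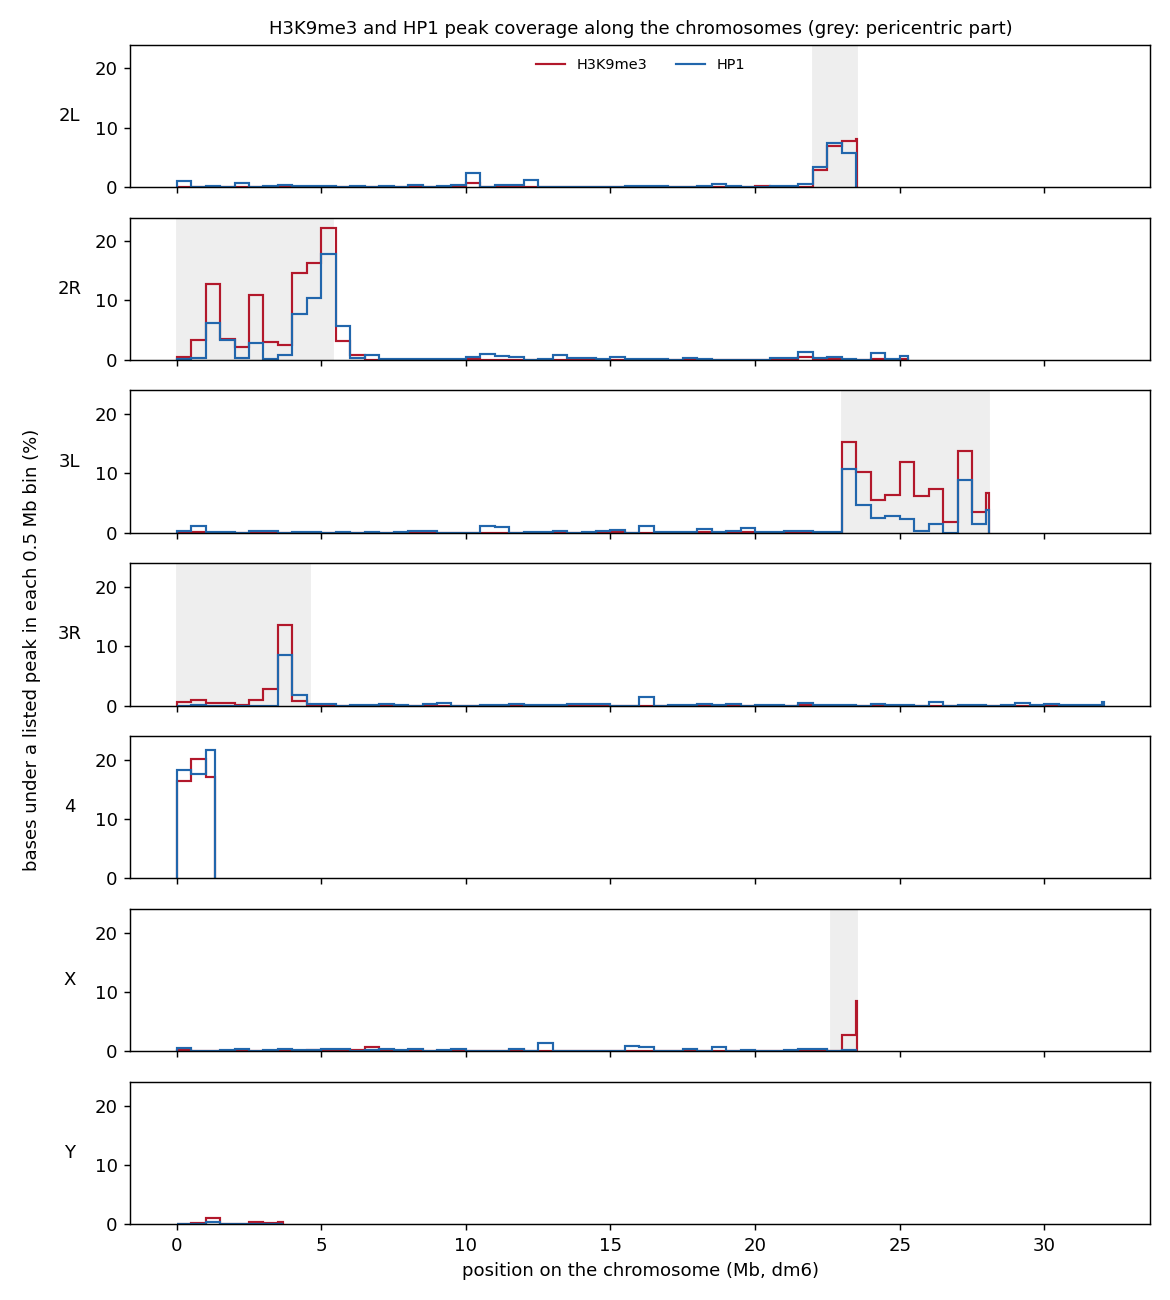
Share of bases under a listed peak in each 0.5 Mb bin (y axis, percent) along each chromosome (x axis, Mb), for H3K9me3 (red) and HP1 (blue), with the fixed pericentric parts in grey. Both lists rise in the pericentric parts of 2L, 2R, 3L and 3R and along chromosome 4, and the highest bin, 22.2% for H3K9me3, lies at the pericentric end of 2R.

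The second comparison asked whether HP1 and H3K9me3 marked the same places. The HP1 names are all ywdf and the H3K9me3 names mostly HWT, so the overlap mostly compares different sources. In the pericentric parts 270 of 540 HP1 peaks (50%, 45.7 to 54.3) touched an H3K9me3 peak, against 16% after shifting. On chromosome 4 the share was 146 of 277 (52.7%, 46.6 to 58.7), against 27.6%. In the arms 42 of 612 HP1 peaks (6.86%, 4.99 to 9.16) touched H3K9me3, against 0.145%, so that 570 arm HP1 peaks had no H3K9me3 peak. Each of these shares exceeded the shifts (circular-shift permutation, two-sided p = 0.002, the smallest the shifts can give). The arm share was lower than the pericentric share (Fisher's exact test, adjusted p = 6.55e-64) and than that of chromosome 4 (adjusted p = 9.29e-51), whereas pericentric and chromosome 4 shares did not differ past the threshold (adjusted p = 0.506). These tests compare raw shares, and the arms held 137 H3K9me3 peaks to touch, against 1870 in the pericentric parts. Over the shifts the order was reversed, with folds of 47.2 in the arms, 3.13 in the pericentric parts and 1.91 on chromosome 4. The sizes of the raw shares also depend on the choices made. The arm share was 14.9% with pericentric parts 0.5 Mb smaller and 4.04% with them 0.5 Mb larger. With at least 50% of the HP1 peak covered the arm and pericentric shares were 3.10% and 31.3%, and with at least 50% of both peaks 2.45% and 21.1%.

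Seen from H3K9me3, the order of the compartments was different. Of the 137 arm H3K9me3 peaks, 55 (40.1%, 31.9 to 48.9) touched HP1, more than the 17.2% of pericentric peaks (Fisher's exact test, adjusted p = 1.96e-09). The arm share was below the 56.0% on chromosome 4 (Fisher's exact test, adjusted p = 0.00536). After shifting, the shares were 0.668% in the arms, 5.35% in the pericentric parts and 32.4% on chromosome 4. Raw shares depend on peak numbers: the arms held 612 HP1 peaks, and the pericentric parts 540 for 1870 H3K9me3 peaks. By source, 23.8% of the 2047 H3K9me3 peaks named HWT and 6.57% of the 198 named ywdf touched HP1, a difference that was not tested. The sources differ in compartment, since 187 of the 198 were pericentric. Within the pericentric parts the shares were 18.4% for HWT and 6.42% for ywdf. In bases, 38.9% of the HP1-covered and 31.4% of the H3K9me3-covered sequence was common to both lists. Arm HP1 peaks within 1 Mb of a pericentric part touched H3K9me3 in 20 of 73 cases (27.4%), and those farther out in 22 of 539 (4.08%). With at least 50% of both peaks required to overlap, 11.7% of all HP1 peaks were shared, compared with 32.1% at 1 bp.

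**Figure D2:**
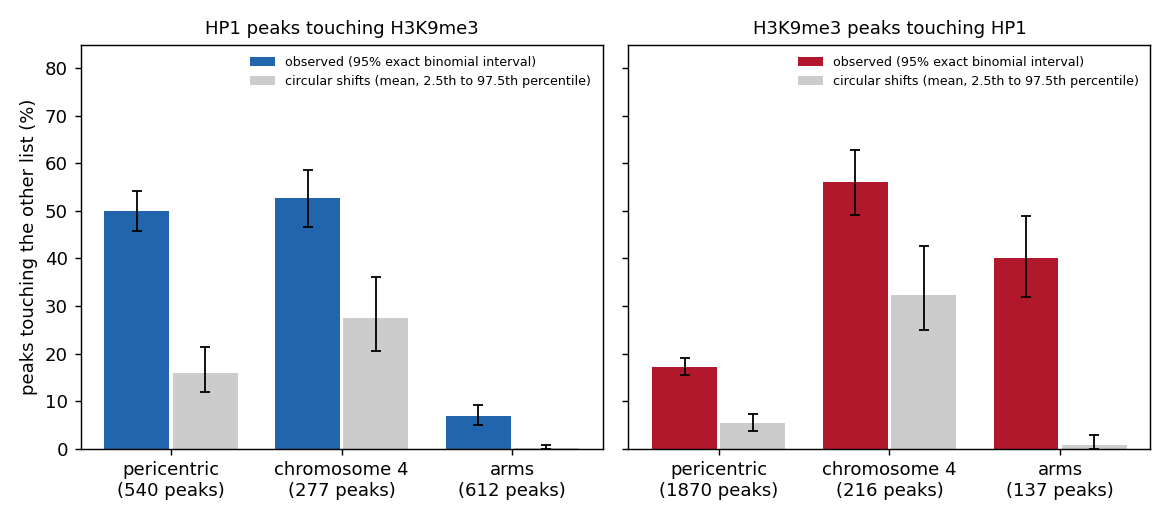
Percent of peaks touching the other list (y axis) by compartment (x axis), for HP1 peaks (left) and H3K9me3 peaks (right); coloured bars are observed shares with exact binomial 95% intervals, and grey bars are means of circular shifts with the range of their central 95%. Observed shares exceed the shifts in each compartment, and the HP1 share falls from 50% in the pericentric parts to 6.86% in the arms.

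Of the 23 genes of the fixed pericentric list, 19 held at least 1 bp of both H3K9me3 and HP1 peaks somewhere in the gene body. In some of these genes no base was common to both lists. H3K9me3 peaks fell in 20 of its 23 genes and HP1 peaks in 21, against 1.12% and 3.56% of all other protein-coding genes (Fisher's exact test, adjusted p = 9.51e-35 and 5.66e-28). RpL15, RpL38 and RpL5, which encode ribosomal proteins, had 91.4%, 42.4% and 32.9% of their bodies under HP1, and 16.7%, 31.5% and 2.54% under H3K9me3. Yeti had 26.7% of its body under HP1 and no H3K9me3 peak within the body, but its HP1 peak touched an H3K9me3 peak beyond it. With at least 10% of the gene body required, 6 of the 23 genes qualified for H3K9me3 and 5 for HP1. The list was chosen by chromosome position, and of all 211 pericentric protein-coding genes 85 (40.3%) held H3K9me3 and 108 (51.2%) HP1.

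On chromosome 4, HP1 peaks fell in 71 of 80 protein-coding genes and H3K9me3 peaks in 56, and all 56 also held HP1. In the fixed chromosome 4 list, 26 of 30 genes held HP1, against 3.53% of all other protein-coding genes (Fisher's exact test, adjusted p = 6.43e-33). H3K9me3 fell in 20 of the 30, against 1.12% (Fisher's exact test, adjusted p = 4.99e-31). The list was chosen by chromosome, so these tests restate its position. Its shares, 86.7% for HP1 and 66.7% for H3K9me3, were near those of all 80 genes, 88.75% and 70%. MED26, a Mediator subunit gene at 4 778516 to 788978, had 80.2% of its body under H3K9me3 and 50.7% under HP1. The corresponding shares were 46.3% and 68.0% for Zip102B, 67.5% and 34.4% for the ligand gene Ephrin, and 66.7% and 22.5% for the adaptor gene Crk. The 4 list members under neither mark were ey and toy, which encode Pax6-type transcription factors of eye development, Sox102F and Actbeta.

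**Figure D3:**
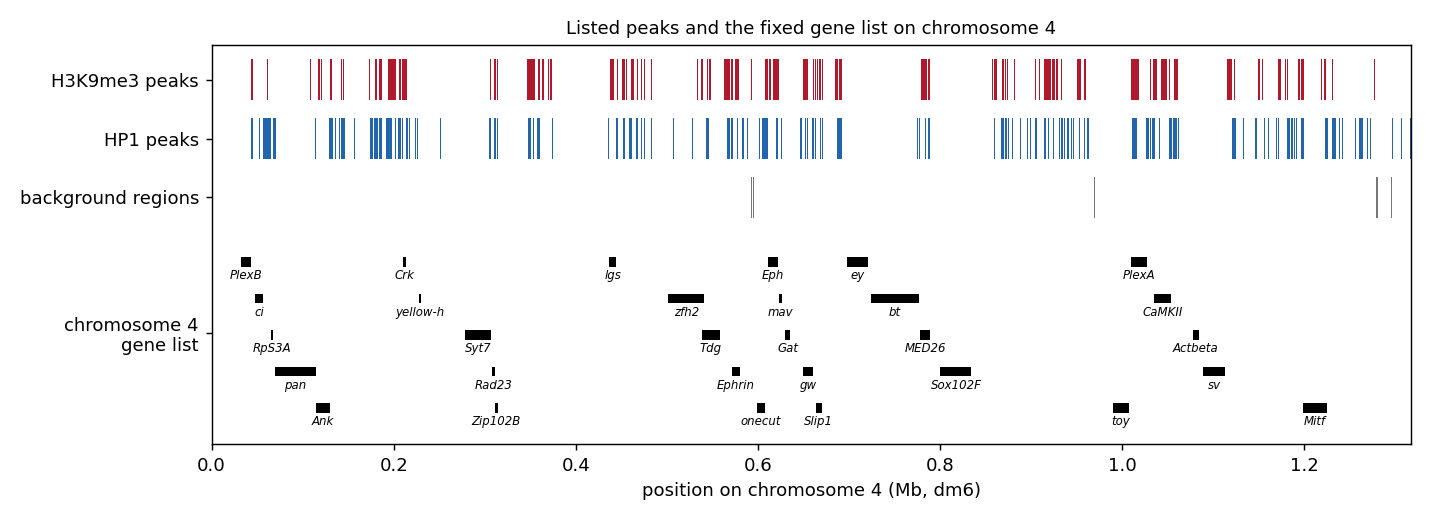
Map of chromosome 4 (x axis, Mb) with H3K9me3 peaks (red), HP1 peaks (blue), background regions (grey) and the bodies of the fixed gene list (black, staggered for legibility). Peaks of both lists run along the chromosome with several gaps, and ey, toy, Sox102F and Actbeta lie in gaps of both lists.

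The remaining lists lay almost wholly in the arms and held few H3K9me3 peaks. No H3K9me3 peak fell in the 22 Polycomb target genes, the 24 wing disc patterning genes, the 13 protein-coding heat shock genes, the 19 heterochromatin factor genes or the 20 germline genes. Only 34 of 13631 protein-coding arm genes (0.249%) held one, so lists of this size could not show a lack. HP1 peaks fell in 5 of 24 wing disc patterning genes (20.8%, 7.13 to 42.2) against 3.68% of other genes (Fisher's exact test, adjusted p = 0.0052). These were sd, with 4.72% of its body covered, ptc, the Hedgehog receptor gene, with 2.31%, bi with 1.01%, ct with 0.376% and hth with 0.278%. Against random lists matched on gene length the expected share was 12.7% and the adjusted p 0.699, so the call was lost. With at least 10% of the gene body required, 0 of 24 qualified.

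HP1 fell in 3 of 22 Polycomb targets (Fisher's exact test, adjusted p = 0.123), with 7.92% of en covered and under 1% of Antp and inv. Among heterochromatin factors 2 of 19 held HP1 (Fisher's exact test, adjusted p = 0.337). These were the gene that encodes HP1a itself, at 2L 8209626 to 8211122, with 66.1% of its body under an HP1 peak, and wde with 10.2%. Among 20 housekeeping genes 2 held HP1 (Fisher's exact test, adjusted p = 0.337). ATPsynbeta, on chromosome 4, had 83.4% of its body under HP1 and 46.2% under H3K9me3, and eEF1alpha1, a translation elongation factor gene on 2R, had 17.6% under HP1 and no H3K9me3 peak. Heat shock and germline genes held no HP1 peak, where 3.71% of other protein-coding genes did. Lists of 13 and 20 genes are too short to show a lack.

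Among arm genes under a listed peak, HP1 without a listed H3K9me3 peak was the commonest class. The 2 lists differ in source and cutoff, so this counts listed peaks and not chromatin states. The smallest −log10 q-value was 5.02 in the HP1 list and 1.38 in the H3K9me3 list. HP1 peaks fell in 338 of 13631 protein-coding arm genes and H3K9me3 peaks in 34, with 25 genes holding both and 313 holding HP1 without H3K9me3. The most bases under HP1 peaks that touched no H3K9me3 lay in tara (5415 bp), Ugt50B3 (5331 bp), arr (3255 bp), tna (2374 bp), Bx (2338 bp), shn (2286 bp), jing (2149 bp) and chn (2096 bp). Of these, arr encodes a Wingless co-receptor, and shn, jing and chn encode zinc-finger proteins. The gene tara, at 3R 16225651 to 16260329, carried 7 HP1 peaks of fold enrichment up to 15.9. Long genes collect more bases under this rule.

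Shared arm peaks covered the most bases in stw (7033 bp), which encodes a laccase, and in the neighbouring HMG-box genes HmgZ and HmgD (3392 bp each), whose annotated bodies overlap, so that their peaks cannot be assigned to either gene. They were followed by Ir31a (2560 bp), Tis11 (2333 bp), psq (2036 bp), Ugt50B3 (1858 bp) and CG8245 (1603 bp). HP1 covered 97.2% of the ionotropic receptor gene Ir31a, at 2L 10405565 to 10408197, and H3K9me3 22.1%. H3K9me3 peaks without HP1 covered the most bases in stw (2312 bp), CG30440 (1709 bp), CG34417 (968 bp), CG44774 (959 bp), sov (957 bp), Ugt50B3 (794 bp), CG33225 (671 bp) and CG14439 (608 bp). Of these genes, stw, CG30440, Ugt50B3 and CG8245 lie in the run of peaks next to the 2R pericentric end.

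Among arm peaks, the 5 widest of H3K9me3 lay on 2R between 5412841 and 5665413, the widest of them 2392 bp at 5464092 to 5466483, outside annotated genes. The widest HP1 peak of the arms spanned 7327 bp at 2R 5662659 to 5669985 over Not3, lncRNA:CR45472 and CG8245. It was followed by peaks of 4636 bp in stw, 2978 bp at 3L 619016 to 621993, overlapping lncRNA:CR43337, 2775 bp at 2R 5606077 to 5608851 and 2568 bp over Ir31a. The 2775 bp peak reached only 217 bp into CG17508. Each of these 10 arm peaks touched the other list.

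Arm peaks were then compared by their position relative to genes. Of shared HP1 peaks 54.8% lay within 200 bp of a gene end, against 31.6% of HP1 peaks without H3K9me3 (Fisher's exact test, adjusted p = 0.00457), while 73.8% and 73.7% lay in gene bodies (adjusted p = 1). Of shared H3K9me3 peaks 38.2% lay near a gene end, against 9.76% of those without HP1 (Fisher's exact test, adjusted p = 0.000385), and 69.1% against 37.8% lay in gene bodies (adjusted p = 0.000911). The HP1 difference at gene ends did not pass the threshold with a reach of 500 bp (Fisher's exact test, adjusted p = 0.141) or with at least 50% of the peak covered (adjusted p = 0.216). The H3K9me3 difference at gene ends did not pass with pericentric parts 0.5 Mb larger (Fisher's exact test, adjusted p = 0.0618), nor did that in gene bodies with the stricter q-value (adjusted p = 0.107). Shared arm peaks were also wider, with a median of 1137 bp against 347 bp for HP1 and 457 bp against 331 bp for H3K9me3 (permutation test, adjusted p = 4e-05 and 0.0305), and a wider peak reaches a gene more easily. By the middle base of each peak, 16.7% of shared and 18.2% of unshared HP1 peaks lay within 200 bp of a gene end (Fisher's exact test, adjusted p = 1), so the HP1 difference was lost. For H3K9me3 the shares by the middle base were 16.4% and 2.44% at gene ends (adjusted p = 0.0284 by the exact test), which passed, and 54.5% and 36.6% in gene bodies (adjusted p = 0.0706), which did not.

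Shared peaks were wider and more enriched than unshared ones in each list. Shared HP1 peaks had a median width of 937.5 bp against 354 bp, and a median fold enrichment of 7.37 against 5.50. Shared H3K9me3 peaks had a median width of 571 bp against 343 bp, and a median fold enrichment of 8.26 against 5.12 (permutation test, adjusted p = 1e-05 for all 4, the smallest it can give). A wider peak has more room to touch another. The tests also count parts of 1 call as separate peaks, although such parts carry the same fold enrichment. The 1435 HP1 peaks carry 1022 call names and the 2245 H3K9me3 peaks 1772, and parts were not joined for this comparison. Within chromosome 4 the HP1 fold enrichment was 6.09 against 5.53 and did not pass the threshold (permutation test, adjusted p = 0.446), nor did it pass over all compartments with at least 50% of the peak covered (adjusted p = 0.459).

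The background regions lay mostly apart from the HP1 peaks. Of 494 regions in the compartments, 15 touched HP1 (3.04%, against 2.37% after shifting, permutation p = 0.504) and 58 touched H3K9me3 (11.7% against 6.14%, p = 0.00599). For H3K9me3 the pericentric regions, 46 of these 58, did not pass alone (17.3% against 10.6%, permutation p = 0.0679), and the arm regions did (2.45% against 0.119%, p = 0.002). In the pericentric parts 0 of 266 regions touched HP1, against 8.70 regions after shifting (permutation p = 0.004), and in the arms 15 of 204 did, against 1.02 (p = 0.002). Of the 612 arm HP1 peaks, 15 (2.45%) touched a background region.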

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

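No paired analysis was possible because the peak lists carry no values of single replicates; for the same reason no replicate could be left out and depth per library is unknown. Of 113 tested alternative values, 96 kept their direction and their side of the threshold. Part of the 96 come from gene lists with no gene under a peak, whose result could hardly change. Others come from the pericentric and chromosome 4 lists, which were chosen by position. The count therefore overstates how stable the other results are. Of 17 without a test, 12 stayed within the 95% interval of the reported value. Fragments joined by call, H3K9me3 peaks named HWT alone, local shifts, changed pericentric ends for overlap and features, the middle base of a peak, the arm against pericentric comparison and width and fold within compartments were chosen after seeing the data. Except where stated, the cause of the changes below was not tested. With reciprocal overlap of at least 50%, 11.7% of HP1 peaks were shared. With pericentric parts 0.5 Mb smaller, the folds over the arms were 27 (pericentric) and 83.1 (chromosome 4) for H3K9me3, and 6.71 and 47.7 for HP1, because the arms then held more peaks. Unshared minus shared HP1 peaks at gene ends differed by -13.4 points at 500 bp and -14.7 with at least 50% of the peak covered, short of the threshold, and by 1.58 points, the opposite direction, by the middle base of each peak, where width gives no advantage. For H3K9me3 the difference was -21.1 points at gene ends with pericentric parts 0.5 Mb larger and in gene bodies -24.2 with the stricter q-value and -18 by the middle base, all short of it. Wing disc patterning genes exceeded other genes under HP1 by 4.98 points within 500 bp of a gene end and 8.18 against length-matched lists, both short of the threshold, and the difference was -1.24 points, the opposite direction, with at least 10% of the gene body covered. The higher fold enrichment of shared HP1 peaks was 0.281 with at least 50% of the peak covered and 0.555 on chromosome 4, both short of the threshold. With neither value past the threshold, 5 values changed direction. They were unshared minus shared HP1 peaks in gene bodies (16.3 points both with at least 50% of the peak covered and by the middle base), Polycomb targets under HP1 (-1.24 with at least 10% of the body covered), heterochromatin factors under H3K9me3 (4.03 within 500 bp of a gene end) and housekeeping genes under H3K9me3 (-0.25 in the arms). Background regions touching HP1 passed it when restricted to the arms, at 7.35%. The lower share of HP1 peaks with H3K9me3 in the arms than in the pericentric parts passed under all 9 alternatives. None of them adjusts for the fewer H3K9me3 peaks in the arms, so they do not test that reading. The arm share ranged from 2.45% (at least 50% of both peaks) to 14.9% (pericentric parts 0.5 Mb smaller). The pericentric share ranged from 21.1% (at least 50% of both peaks) to 60.7% (fragments joined by call).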

Other observations

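The regions in this part, the shares of call numbers, the share of arm HP1 peaks touching a background region, the test of gene ends and the comparison by the middle base were chosen after their values were seen. Among the 34 arm genes with H3K9me3, the gene ova, at 2L 10227760 to 10231692, had 25% of its body under H3K9me3 and 30.7% under HP1, at the start of a run of 3 H3K9me3 and 4 HP1 peaks that also spanned eEF1delta and mthl15. The gene sov, at X 6756322 to 6770712, had 10.5% of its body under H3K9me3 and 3.02% under HP1. The flamenco piRNA locus, annotated as lncRNA:flam at X 21631891 to 21790731, held 3 H3K9me3 peaks of fold enrichment up to 23.5 and 1 HP1 peak. On 2R, 9 H3K9me3 peaks lay at 6419737 to 6491122, outside annotated genes, with a fold enrichment up to 16.9, and 1 touched HP1.

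Call numbers in the peak names rose with position on each chromosome. In the HWT part of the H3K9me3 list, 8.60% of the numbers spanned in the arms were listed and 65.7% in the pericentric parts (Fisher's exact test, p = 2.64e-262). In its ywdf part the shares were 9.21% (7 of 76 numbers) and 5.95% (157 of 2640), a difference that was not tested. Numbers were counted only from the first to the last listed call of each chromosome part, so each share is an upper limit. In the ywdf arms this left 68 numbers on X, 7 on 2R, 1 on 2L and none on 3L or 3R. The ywdf shares of arms and pericentric parts therefore cannot be set against each other. For HP1 the shares were 8.25% and 21.7% (Fisher's exact test, p = 4.75e-47), and for the background list 40.1% and 85.3%, not tested. Counts of peaks by compartment therefore describe what was listed, not all calls. HP1 listed 3 mitochondrial peaks over 1458 bp, and the background list 6 over 11559 bp.

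Most arm HP1 peaks lacked an H3K9me3 peak. In the pericentric parts 0 of 266 background regions touched HP1, against 8.70 after shifting, so HP1 peaks there may have been cleared of them. Arm HP1 peaks touched such regions more often than chance placement gives, since 15 of 204 arm regions touched HP1 against 1.02 after shifting. Few of the arm HP1 peaks without H3K9me3, 2.63% (1.48 to 4.30), touched a listed background region. This share decides little about the source, because the arms held only 204 regions for 570 such peaks. Background calls left off the list stay open, since 40.1% of those spanned in the arms were listed and 13.5% (10.8 to 16.6) of these HP1 peaks lay between background regions of consecutive call numbers, where no unlisted call can be. Weak HP1 calls stay open too, with values on both sides. Arm HP1 peaks had a median fold enrichment of 6.07, against 5.71 in the pericentric parts and 5.94 on chromosome 4. With the stricter q-value in both lists, 6.31% of arm HP1 peaks touched H3K9me3, against 51.9% of pericentric ones. Of arm HP1 peaks of fold enrichment 7.67 or more, 9.76% touched H3K9me3 (6.06 to 14.7), and of those of 4.68 or less 5.88% (3.08 to 10.1). The bound of 25% set in advance for the stronger group decides nothing, because all 42 touching peaks of the arms would make up only 20.5% of it. Unshared HP1 peaks had a median fold enrichment of 4.58 in the pericentric parts and 5.53 on chromosome 4. The arm HP1 peaks without H3K9me3 had 6.03, against 7.51 for the shared arm peaks (permutation test, adjusted p = 0.0305), as weak calls would give. That test counts parts of 1 call as separate peaks. Unlisted HWT H3K9me3 calls stay open as well: 2.63% of these HP1 peaks lay between H3K9me3 peaks of consecutive call numbers, where no further HWT call can be, the median gap held 63 unlisted numbers, and unlisted ywdf calls were not placed. No biological explanation was tested, since the HP1a chromodomain mutant and K9R libraries were not analysed here.

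In the pericentric parts 270 HP1 peaks had no H3K9me3 peak. Of these, 31.1% (25.6 to 37.0) lay between HWT H3K9me3 peaks of consecutive numbers, so no further HWT call could lie beside them. Unlisted parts of the neighbouring HWT calls still could, because many listed intervals are parts of a call. Of these 84 peaks, 7 lay between parts of 1 HWT call. Unlisted ywdf H3K9me3 calls, or unlisted parts of HWT calls, may lie beside any of the 270, and unlisted HWT calls beside the others. This cannot be told apart from HP1 without H3K9me3.

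A hypothesis from these lists is that arm HP1 peaks, those without H3K9me3 included, may favour gene ends. Of 570 such peaks 31.6% lay within 200 bp of a gene end, above the 14 to 20.7% of 1000 shifts (permutation, two-sided p = 0.002, the smallest they can give), and above the 16.7% (11.8 to 22.5) of arm background regions. Shared arm HP1 peaks lay there in 54.8% of cases, but they were wider (median 1137 bp against 347 bp). The difference from unshared peaks did not pass with a reach of 500 bp (Fisher's exact test, adjusted p = 0.141) or with at least 50% of the peak covered (adjusted p = 0.216), and it was lost by the middle base of each peak (16.7% against 18.2%, adjusted p = 1). The difference from the background regions was not tested. Open chromatin at promoters, which CUT&RUN can release without a specific antibody, was not tested either, so the position alone does not separate binding from digestion.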
